A study of Stylosanthes guianensis with 3 samples.

How the data were processed

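Transcript levels were measured by RNA sequencing in 3 root samples of Stylosanthes guianensis (stylo, a tropical forage legume), genotype RY5. All 3 carry the label EV-Mn and form 1 group. Per the series' design text, the plants were composites whose hairy roots were induced with Agrobacterium rhizogenes carrying the empty binary vector pFGC5941. The same text names roots overexpressing SgUBC2 as the other arm. Those roots were not analysed here, so no comparison between overexpression and empty vector was made. The series title names manganese toxicity, but the labels used here give no manganese dose or time. The labels do not say whether the 3 samples came from separate plants or harvests, so the spread between them may be partly technical.

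RNA was extracted with TRIzol and its integrity checked on an Agilent instrument, and libraries followed standard Illumina protocols, per the labels' protocols. Bowtie2 2.2.3 is listed in the submitters' processing notes, with no role given. Each file holds 1 column of values for 145088 features, rounded to 2 decimals. The authors deposited these values as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file names. The feature names have the form that the Trinity assembler gives to genes of a de novo assembly. They were grouped here by the DN number alone, leaving out the c and g parts of the name. This gave 87331 groups, called Trinity components here, of which 67863 hold 1 gene. The grouping is wider than one that keeps the c part, so genes in 1 group need not be close copies. The quantifier, the assembly settings and any filter are not given in the sources used here. FPKM already divides by transcript length and library total, and reads shared by close copies in 1 component can be split between genes by the quantifier.

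The files do not pair these identifiers with gene names, and the assembly and its annotation were not used here. The 26 gene lists fixed before the data were examined (metal transport, antioxidant enzymes, ubiquitin conjugation and ligation, phenylpropanoid synthesis, markers of other tissues and organisms, and others) were defined on gene descriptions, so none of them was scored. The rule for named genes, also fixed before the data were examined, took the 10 genes of highest mean FPKM, the 5 of largest SD of log2(FPKM + 1) among genes with a mean of at least 10, and the leading members of each list. Only the first 2 identifiers of each of the first 2 parts are printed, because an identifier without a name says little, and the others are summarised. Identifiers outside the rule are marked where they appear.

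From the FPKM values, a gene was counted as detected at an FPKM of 1 or more. Agreement between libraries was the Pearson and Spearman correlation across the 88715 genes above 0 in any library, on log2(FPKM + 1). These correlations are across genes, which are not independent replicates, and carry no p-value. Genes were counted as varying when the highest library was at least 2-fold above the lowest on the value + 1 scale, among genes with a mean FPKM of at least 10. A pseudocount of 1 understates the change of low genes. With 1 group there was no test between groups, and no p-value is reported. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

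No read totals were in the files, and transcript lengths were not used, so the absolute depth of each library is unknown and no counting interval is given. Relative depth was read from low values. For genes with few reads, the ratio of FPKM between a pair of libraries takes discrete values, and its mode gives the relative worth of 1 read. Among the 10561 genes between 0.5 and 3 FPKM in both libraries 1 and 2, the fullest bin of 0.02 on the log2 scale held 686 genes, against a median of 27 per occupied bin. Library 2 then had 1.00 times, and library 3 had 0.872 times, the depth of library 1. Compared directly, library 3 had 0.873 times the depth of library 2 in this range and 0.867 times at 0.3 to 0.6 FPKM. At 1 to 5 FPKM the fullest bin for that pair gave 1.01 times and held 210 genes, which does not go with the other estimates, so the relative depth of libraries 2 and 3 depends on the range used. The estimates for libraries 2 and 3 over library 1 in that range were 1.00 and 0.873. This assumes equal effective lengths in the libraries. Whole reads were not reconstructed, since the step in FPKM depends on each gene's length.

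The scripts were tested on simulated data made from the real genes' means. Of 200 genes set 4-fold higher in 1 simulated library, 100% were counted as varying, and of the unchanged genes 0% were. The simulated noise was set below the real spread, where the median SD was 0.14 on log2(FPKM + 1) at a mean of at least 10 FPKM. These outcomes follow from that setting, so they check the code and give no error rate for the real genes. A simulated library 3 mixed from the other libraries at a weight of 0.6 was placed at 0.599. The alternatives tried were other FPKM minima, pseudocounts of 0.1 and 0.01, a minimum mean FPKM, rescaling to a total of 1000000 (TPM), median-of-ratios scaling, leaving out each library, and, chosen after seeing the data, sums over Trinity components.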

Results

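Roots of stylo composite plants carrying the empty vector were profiled in 3 RNA-seq libraries, all of the group labelled EV-Mn, called libraries 1, 2 and 3 after the numbers in their labels. This group is the control arm of a study on SgUBC2, named for a ubiquitin-conjugating enzyme, a class of proteins that passes ubiquitin to targets. The overexpression arm was not analysed here. Control refers here to the empty vector alone. The series title names manganese toxicity, so the Mn of the label may mean that these roots were exposed to manganese. The labels used here do not describe the exposure, and the roots are not to be read as untreated. The data therefore describe the levels of assembled genes in the empty vector roots and how far the 3 libraries differed. Genes are given by assembly identifier, since the files do not pair identifiers with names.

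Of the 145088 assembled genes, 45953 were above 0 in all 3 libraries and 56373 (38.9%) were at 0 in all of them. A level of 1 FPKM or more was reached by 29665 ± 2102 genes per library (SD, n = 3), and 23700 genes reached it in every library. Library 2 had the most detected genes, with 31864 at 1 FPKM or more, followed by library 3 with 29456 and library 1 with 27676. The order was the same for genes above 0, at 72463, 64405 and 60442 genes in libraries 2, 3 and 1. The relative depth of libraries 2 and 1, read from the worth of a single fragment, was 1.00, and that of libraries 3 and 1 was 0.872. At higher levels the libraries were closer, with 1514 ± 24.0 genes (SD, n = 3) at 100 FPKM or more. Summed FPKM was 924613 in library 1, 924619 in library 2 and 914888 in library 3.

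**Figure D1:**
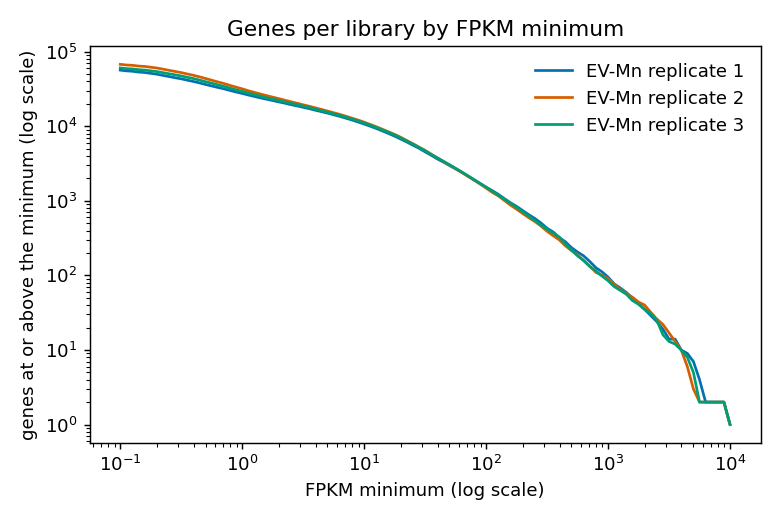
Number of assembled genes at or above each FPKM minimum, both axes logarithmic, with 1 line per EV-Mn library. The lines part at low minima, where library 2 has 31864 genes at 1 FPKM or more and library 1 has 27676, and lie close at 100 FPKM, with 1486 to 1529 genes.

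The 10 highest genes of each library held 6.55% ± 0.268 of summed FPKM (SD, n = 3), and the 100 highest held 23.2% ± 0.457 (SD, n = 3). With genes summed over their Trinity components, the top 10 components held 10.005%. The gene of highest mean level, TRINITY_DN87319_c1_g3, stood at 11319 ± 1754 FPKM (SD, n = 3), with 13052 in library 1, 9545 in library 2 and 11361 in library 3. The next, TRINITY_DN85232_c3_g1, stood at 10475 ± 1940 FPKM (SD, n = 3) and ran the other way, with 9225 in library 1, 12710 in library 2 and 9491 in library 3. Their means differed by less than the SD of either, so these libraries do not rank them. The 10 genes of highest mean ranged from 4062 to 11319 FPKM, with a coefficient of variation between 5.38% and 18.9%. In 7 of these 10 genes library 2 had the lowest value of the 3, and in the other 3 it had the highest. Among the latter, TRINITY_DN85232_c3_g1 shares its DN number, but not its c part, with another of them. Genes with a mean under 1 FPKM held 1.47% of summed FPKM in library 1, 2.35% in library 2 and 1.81% in library 3. Of the 28091 genes with a mean of at least 1 FPKM, 21319 (75.9%) shared a Trinity component, that is a DN number, with another gene. How many also shared the c part was not counted. The levels of such genes are uncertain where reads were split between close copies.

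The 3 libraries were compared with each other to measure the spread within the control group. On log2(FPKM + 1), Pearson's r across genes was 0.968 between libraries 1 and 3, 0.958 between libraries 2 and 3 and 0.951 between libraries 1 and 2. Spearman's rho across the same genes was 0.713, 0.682 and 0.671, in the same order. The ranks were closer among genes with a mean of at least 1 FPKM, where rho was 0.958 between libraries 1 and 3, 0.944 between libraries 2 and 3 and 0.925 between libraries 1 and 2. No pair of files held identical values. The median SD over the 3 libraries, among the 11139 genes with a mean of at least 10 FPKM, was 0.14 on the log2(FPKM + 1) scale, and the 95th percentile was 0.60.

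Among these 11139 genes, 736 (6.61%) differed by at least 2-fold between their highest and lowest library. Libraries 1 and 2 differed by at least 2-fold in 720 genes, of which 560 were higher in library 1 and 160 higher in library 2. Libraries 2 and 3 differed in 360 genes, of which 342 were higher in library 3. Libraries 1 and 3 differed in 34 genes, of which 8 were higher in library 1. Median-of-ratios scaling moved library 2 by 0.25 and library 3 by 0.13 on the log2 scale relative to library 1. After it, 813 genes differed between libraries 1 and 2, and the share higher in library 1 was 91.9% in place of 77.8%. Between libraries 1 and 3 the majority then changed sides, with 25 of 38 genes higher in library 1. The scaling was set by all genes above 0 in every library, many of them low. Among the 11139 genes counted here, the unscaled median of library 1 minus library 2 was -0.139 on log2(FPKM + 1). That of library 1 minus library 3 was -0.065. The scaling was larger than either shift, so the scaled counts lean toward library 1 in part for that reason. No p-value goes with these counts, since each library is a single sample.

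The genes of largest spread were high in library 1, intermediate in library 3 and low in library 2. TRINITY_DN88449_c3_g1 had 286 FPKM in library 1, 172 in library 3 and 1.59 in library 2, an SD of 3.73 on the log2(FPKM + 1) scale (n = 3). TRINITY_DN82417_c9_g6 had 1012 FPKM in library 1, 580 in library 3 and 10.9 in library 2, an SD of 3.49 on that scale (n = 3). The 5 genes of largest SD all had this order, but TRINITY_DN88449_c3_g1 shares its Trinity component with another of them, so they may not be separate genes. A set of 210 genes was at least 4-fold higher in library 1 than in library 2, and it held 5.76% of summed FPKM in library 1, 3.63% in library 3 and 0.768% in library 2. The reverse set held 6 genes. For the varying genes, the library farthest from the mean of the other libraries on log2(FPKM + 1) was library 2 in 607 cases, in 542 of which it was lower. It was library 1 in 126 cases, in 106 of which it was lower. It was library 3 in 3 cases, TRINITY_DN76072_c0_g2, TRINITY_DN86749_c1_g1 and TRINITY_DN85803_c3_g1, which are named here after their values were seen. On this scale a library midway in FPKM lies nearer the higher of the others, so the lowest tends to come out farthest. These counts therefore do not mark library 2 as an outlier. The 360 genes for libraries 2 and 3 against 34 for libraries 1 and 3 carry the same limit.

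Library 3 lay strictly between libraries 1 and 2 in 68.6% of the genes with a mean of at least 10 FPKM, where 33.3% would follow if each library were equally likely to be the middle one. Library 1 was the middle one in 16.6% and library 2 in 14.5% of these genes. Among lower genes above 0 in all libraries, library 3 was the middle one in 44.8% at a mean of 1 to 3 FPKM and 54.0% at 3 to 10. The means and SDs given over 3 libraries therefore include a library whose values, at a mean of at least 10 FPKM, fell mostly inside the range of the other libraries.

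**Figure D2:**
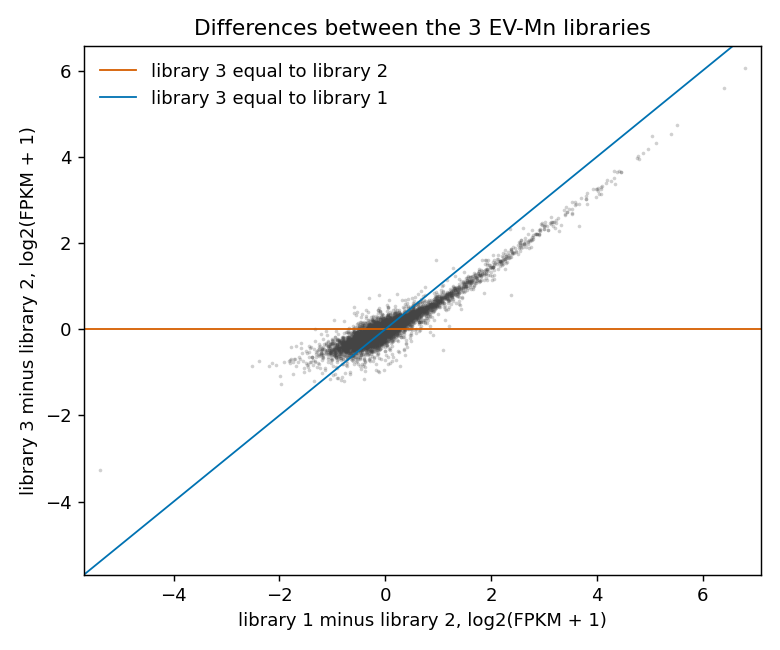
Each point is 1 of the 11139 genes with a mean of at least 10 FPKM; the horizontal axis is library 1 minus library 2 and the vertical axis library 3 minus library 2, both in log2(FPKM + 1) units. Library 3 lies between the line of equality with library 1 and the line of equality with library 2 in 68.6% of genes.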

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

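The component sums and every alternative for the position of library 3 were chosen after seeing the data, and the other alternatives before the data were examined. The number of genes detected per library followed the minimum, with 61842 at 0.1 FPKM, 15546 at 5 FPKM and 65770 above 0, in place of 29665. Mean Pearson's r between libraries, 0.959, fell to 0.856 with a pseudocount of 0.1 and to 0.695 with 0.01, and ranged from 0.949 to 0.965 when each library was left out. Mean Spearman's rho, 0.689, was 0.942 among genes with a mean of at least 1 FPKM, and 0.650 to 0.682 with each library left out. Leaving out 1 library leaves 1 pair, taken over the genes above 0 in either of its libraries. Both correlations were therefore lower than those of the same pairs in the Results, which include genes above 0 only in the third library. The count of varying genes, 736, was 3688 with a mean of at least 1 FPKM, a range where few reads per gene limit the precision. It was 329 without library 1, 26 without library 2 and 720 without library 3, with the mean level taken over the remaining libraries, so it rested on libraries 1 and 2. Sums over Trinity components gave 14249 detected components, a rho of 0.60, a share of 10.005% for the top 10 and 31.2% for the top 100, and 363 varying components. Leaving aside the position of library 3, 20 of 37 alternatives stayed within the spread between libraries, or within 1.5 times for counts. Some of these could not have come out otherwise. Leaving out 1 of 3 libraries cannot shift a mean over libraries by a full SD, which covers the top shares. The numbers of detected genes per library were also too close for their mean to move 1.5 times. The tally is therefore no measure of how stable the results are. The cause of the shifts beyond these limits was not tested, with 2 exceptions. The pseudocounts and minima act on low genes by construction, and the correlations with 1 library left out use fewer genes. The gene list levels were planned and not run, because the files do not pair identifiers with gene descriptions. No paired analysis was possible because there is 1 group.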

Other observations

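The position of library 3 and the tests in this part were chosen after the results were seen. With 1 group in the design, no biological explanation was tested.

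Library 3 lay at a similar median position between the other libraries for genes that differed in either direction. Over the 720 genes with a mean of at least 10 FPKM that differed at least 2-fold between libraries 1 and 2, the median position of library 3, counted as 0 at library 2 and 1 at library 1, was 0.565, with quartiles of 0.517 and 0.606. It was 0.566 for the 560 genes higher in library 1 (interquartile range 0.0784) and 0.563 for the 160 higher in library 2, where the range was wider at 0.182. The median over all of them was between 0.510 and 0.573 under 7 alternatives of scaling, level and fold. At these levels the values of library 3 were close to a linear mix of the other libraries. For genes of mean FPKM 100 to 300, the robust SD of the log2 ratio of library 3 to that mix was 0.056, against 0.37 for library 1 to library 2. The SD around the mix was 0.52 at 1 to 3 FPKM, 0.23 at 3 to 10, 0.12 at 10 to 30, 0.073 at 30 to 100 and 0.048 at 300 to 1000. It was higher again, at 0.078, in the 87 genes at 1000 FPKM or more. Between libraries 1 and 2 it was 0.80, 0.42, 0.29, 0.30, 0.43 and 0.51 in these classes, so below 10 FPKM the mix left over 0.5 of that spread. Of the 736 genes that differed at least 2-fold between any libraries, 3 had library 3 at least 2-fold off the mix. These genes, named after their values were seen, were TRINITY_DN82107_c1_g14, TRINITY_DN85803_c3_g1 and TRINITY_DN84794_c3_g9, the last with 0.07 FPKM in library 1, 44.0 in library 2 and 3.66 in library 3. This low count does not single out a mix. The weight of 0.565 came from 720 of the 736 genes. Where library 1 is higher, the mix is at least 0.565 of library 1, so even a copy of library 1 would be under 2-fold off. Libraries 1 and 3 themselves differed at least 2-fold in 34 genes.

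Gene-by-gene independent variation of the 3 libraries is argued against, since the interquartile range of the position was 0.0892 and 100 random turns of each gene's deviations gave 0.754 to 0.957. Any difference shared by many genes would fall below the turns, so this does not single out a mix. The interquartile range was also below them for the position of library 1, at 0.198 over 360 genes. The median position of library 1 was -0.743, outside the other libraries. That follows if library 3 lies midway, so it restates the same pattern and is no separate case. For library 2 the range was 1.11 over 34 genes. Reads reused from the other libraries are argued against only weakly as the whole of library 3. In library 3, 1172 genes had 1 FPKM or more and were at 0 in both others, but only 12 such genes had 5 FPKM or more. The same count at 1 FPKM was 997 for library 1 and 1964 for library 2. Most of these genes were thus low, and how the quantifier split reads between close copies was not examined. A pool of RNA, or plants pooled before extraction, may give such a mix, and so may 3 independent samples that differ along a single axis, such as the share of a tissue or a growth state. The spread of 0.056 around the mix goes with both, so these cannot be told apart here, and the labels used here do not say how the samples were drawn. If the libraries are not independent, the SDs over 3 libraries would understate the spread between control roots.

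In the set of 210 genes at least 4-fold higher in library 1 than in library 2, the 189 genes with at least 3 FPKM in library 2 had folds of library 1 over library 2 from 4.10 to 92.6. Both ends are set by the selection, which drops genes under 4-fold and those lowest in library 2. Whether these genes came from another tissue or organism, or from a response that differed between samples, was not tested, since the files do not pair identifiers with names.

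Library 2 had 19.9% more genes above 0 than library 1. Sequencing depth is argued against, since the relative depth was 1.00. A few genes taking most of the reads in library 1 are argued against as the whole cause too. The 100 highest genes held 23.6% of summed FPKM in library 1 and 23.4% in library 2, and the 10 highest held 6.84% and 6.32%. The share of expression in genes with a mean under 1 FPKM was 1.59 times as high in library 2 (95% bootstrap interval over genes 1.57 to 1.62). That interval resamples genes, which are not replicates. It holds no spread between samples and applies to libraries 1 and 2 alone. The 4-fold set would free 1.05 times, and the median factor over genes above 0 in all libraries, from the median of ratios, was 1.19 times. Applied to all genes alike, either falls short of the shift in the low genes. The second factor is itself partly set by low genes. Among genes with a mean of at least 10 FPKM, the median of library 1 minus library 2 was -0.139 on log2(FPKM + 1). A broader set of weakly expressed genes and low-level background such as genomic DNA both stay open and were not tested.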
